A study of Mus musculus with 8 samples.

How the data were processed

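RNA was sequenced from tumour nodules of the lung in 8 libraries of mice of a genetically engineered tumour model on a mixed background. Per the labels' protocols, RNA was isolated from frozen tissue with magnetic particles, treated with DNase, and made into libraries with the TruSeq RNA Access kit, in which probes capture coding regions. The labels name the molecule as polyA RNA. Per the submitters' processing notes, the tools named are bcl2fastq, STAR, featureCounts and DESeq2 and the genome builds are mm10 and GRCm38. Their versions, their order, the gene annotation and whether reads were counted by strand are not given in the sources used here.

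The deposited raw table holds whole-number read counts per gene symbol, unnormalized, with 1 column per library. The deposited normalized table holds a signal per gene in units of scaled reads, and its values are the raw counts divided by 1 factor per library. These factors equal the size factors that DESeq2 gives on the raw counts. Multiplied back, between 99.99% and 100% of the values of a library came out whole within 0.05 reads. The main test was run on the deposited counts. Run on the reads recovered from the normalized table, it called 676 genes in the combination against vehicle, and 1166 genes for JQ1 over both backgrounds.

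Labels of each library gave its treatment, and replicates were numbered in accession order within a group of 2. The labels do not state that the libraries of a group come from separate animals. In the JQ1, anti-PD-1 and combination groups the libraries of a group differ in sex by Xist and Y-linked counts, so they are from different animals, while both vehicle libraries are male. P-values measure the spread between these samples, part of which may be technical. No library was a copy of another: the smallest chi-square per degree of freedom between libraries was 20.9 within groups and 17.7 between groups.

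Total counts ranged from 2719816 in combination replicate 1 to 15224108 in vehicle replicate 2. The table has 52459 symbols, of which 26033 had no count in any library. filterByExpr kept 14085 for testing. Symbols were matched to GENCODE vM21 on GRCm38 for position, biotype, GC content and length: 48108 of all symbols and 13813 of the tested ones matched. Coordinates are 1-based. Counts of 359 genes, annotated as nuclear or mitochondrial ribosomal RNA or overlapping the ribosomal RNA locus of chromosome 17, were summed as the ribosomal RNA share of each library.

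Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust glmQLFit, glmQLFTest) in R 4.3.3, with TMM factors and 1 fit of all 8 libraries with a mean per group, which leaves 4 residual degrees of freedom. The biological coefficient of variation was 0.332. There were 8 contrasts: each treatment and the combination against vehicle, the combination against each single treatment, each treatment averaged over both backgrounds, and their interaction. P-values were adjusted by Benjamini-Hochberg within a contrast, with calls at 0.05, and "rose" and "fell" are used for calls. Fold changes are log2 with a prior count of 0.125, and SE is the standard error of the log2 fold change. CPM are counts scaled by total and TMM factor, given as mean ± SD. Where a side held 1 to 3 counts in all, the ratio of summed counts is given with its 95% counting interval, which covers counting error only.

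Gene lists of pathways and cell types, 43 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over the 37 lists that had at least 5 tested members. Members were also adjusted over the list alone. Medians of a list in a single library are of log2(CPM + 0.5) less the mean of the vehicle libraries. No list call in any contrast holds with an estimated correlation. The groups, contrasts, tests, lists, alternatives and naming rule were written before the data were examined, apart from the camera test of the interaction and the tests, lists and alternatives stated as added.

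The naming rule took the 10 largest rises and 10 largest falls among called genes with mean log2 CPM of at least 1 and no overlap between the sides, for each treatment and the combination against vehicle and for JQ1 over both backgrounds, and the first 5 of each for the others. Where fewer than 5 of a direction passed, the genes with the smallest p filled up to 5 and are given as values. A set of 17 genes was fixed to be reported in any case, and up to 4 members with the smallest p were named per list. Predicted genes, receptor segments, Xist and Y-linked genes were not named by rank. Some items that the rule names are not reported here.

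Alternatives set in advance were RLE and upper-quartile factors, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, limma voom, limma trend on log2(normalized value + 1), a fit of only the libraries compared, a sex term, removal of sex-linked, haemoglobin and receptor segment genes, a 2-group and an additive fit, an estimated correlation, and each library left out in turn. Chosen after seeing the data were removal of ribosomal RNA genes, protein-coding genes only, libraries thinned to equal totals or to equal protein-coding counts, removal of GC and length trends, recovered reads, the ribosomal RNA share as a term, and for lists also the sex term. No column of another sample was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

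The test was run on counts simulated from the real means and library sizes with 200 changed genes, drawn only from genes above a floor on mean CPM. Of 2-fold, 4-fold and 8-fold changes, 1.49%, 55.2% and 89.4% were recovered in the combination against vehicle (13731 genes), with 1 false call. For JQ1 over both backgrounds (13769 genes) 23.9%, 97.0% and 98.5% were, with 11 false calls. These rates hold for the simulated counts and do not vouch for the real calls.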

Results

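Gene expression was measured in lung tumour nodules of a genetically engineered mouse model, in 4 groups of 2 libraries: vehicle, JQ1, anti-PD-1 antibody, and the combination of JQ1 with the antibody. JQ1 blocks the bromodomains of the BET proteins, which bind acetylated chromatin, and PD-1 is an inhibitory receptor of T cells. The design asks how tumour nodules differ after each treatment and after both. Total counts were 12615865 and 15224108 in the vehicle libraries, 8977259 and 9789137 with JQ1, 12998173 and 10318833 with the antibody, and 2719816 and 9034331 with the combination. Of 52459 gene symbols, 14085 had enough counts to test.

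Ribosomal RNA made up more of the counts where JQ1 was given. Its share was 23.4% ± 1.38 (SD, n = 2) in vehicle, 32.1% ± 5.13 (n = 2) with JQ1, 24.4% ± 0.506 (n = 2) with anti-PD-1 and 49.9% ± 4.67 (n = 2) with the combination. Most of it came from Gm42418, a lincRNA on chromosome 17 (39846958 to 39848788, GRCm38), singled out after its values were seen, which took 19.8%, 26.1%, 20.7% and 43.9% of counts in the same order. Gm42418 lies within the ribosomal RNA gene CT010467.1 on the opposite strand, and since strand use is not given, reads of the pair cannot be told apart. Protein-coding genes took 73.4% ± 1.15 of counts in vehicle and 44.9% ± 3.72 in the combination, and beta-actin, Actb, took 2.57% ± 0.138 and 0.677% ± 0.0768. By Xist and Y-linked counts, JQ1 replicate 1, anti-PD-1 replicate 2 and combination replicate 1 are from females and the other 5 libraries from males.

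**Figure D1:**
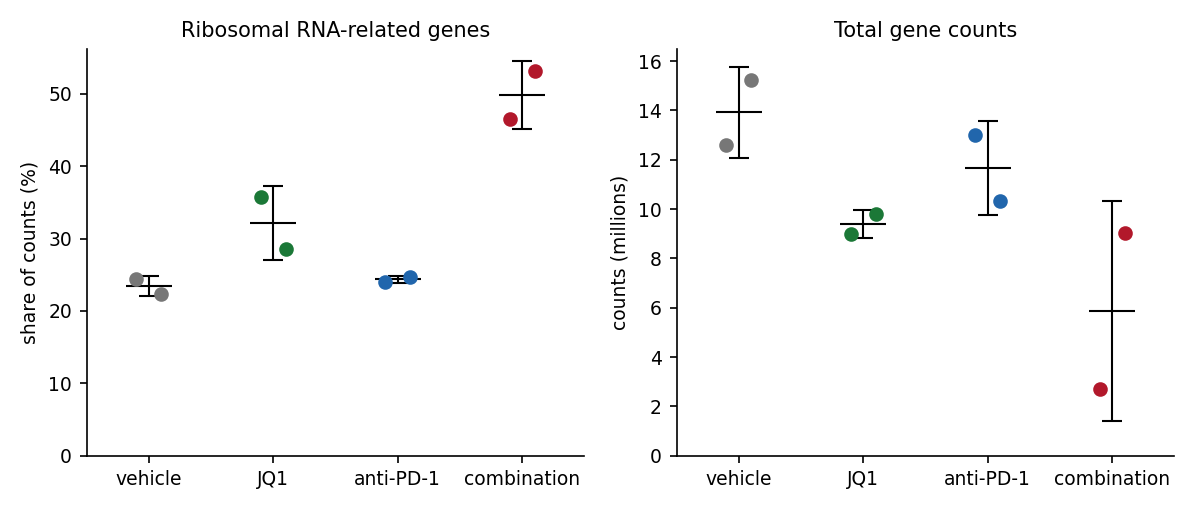
Share of counts from ribosomal RNA genes, in percent, and total counts, with a point per library and group mean and SD as lines. Combination replicate 1 has the lowest total, 2719816, and the combination libraries have the highest ribosomal RNA shares, 46.6% and 53.2%, against 22.4% to 35.7% in the others.

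On a map of distances between libraries, made from the 500 most different genes of each pair, the combination libraries lay apart from the rest. Their positions on the first dimension, which held 27.8% of the variation, were 2.19 and 1.27, against −1.05 to 0.37 for the other 6 libraries. The second dimension held 19.1% and set the combination libraries against each other, at −1.44 and 1.92. Correlations of log2 CPM were 0.926 to 0.980 over the 4 pairs within groups and 0.906 to 0.976 over the 24 pairs between groups.

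**Figure D2:**
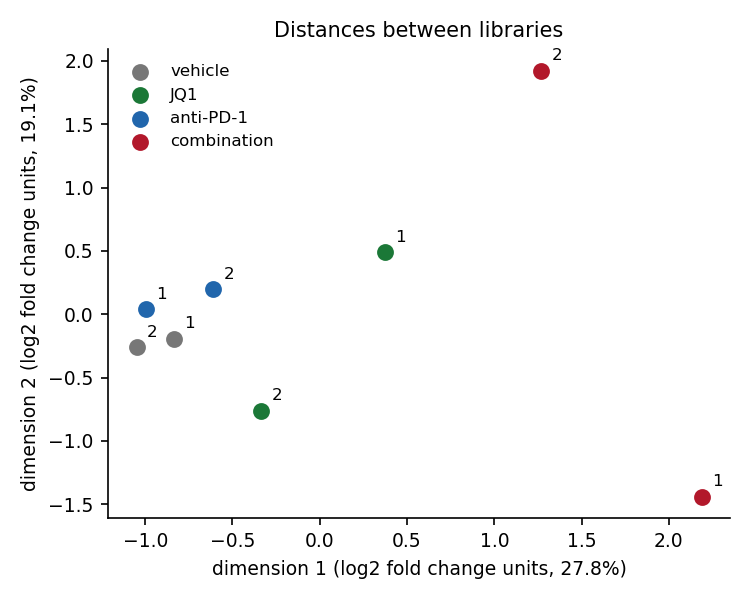
Multidimensional scaling of the 8 libraries, with leading log2 fold change on both axes, a colour per group and replicate numbers beside the points. The combination libraries are at 2.19 and 1.27 on the first dimension, which holds 27.8% of the variation, and vehicle and anti-PD-1 libraries are at −1.05 to −0.61.

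JQ1 against vehicle shows the BET inhibitor alone, and the genes with the smallest p, none of which passed the test, are given as values. Hist1h4c, a histone H4 gene, was at 31.8 ± 6.10 CPM (n = 2) with JQ1 and 94.3 ± 10.2 CPM (n = 2) in vehicle, a log2 fold change of −1.57 (SE 0.27). H2-T-ps, an MHC class I pseudogene on chromosome 17, was at 4.41 ± 0.440 against 39.9 ± 8.43 CPM, and Fgd1, an exchange factor for Cdc42, at 5.24 ± 1.34 against 25.6 ± 3.14 CPM. Slain1, a microtubule protein, was at −2.85. On the other side stood Eps8l3 at 3.48 (SE 0.55), Misp, an actin-bundling protein of the mitotic cortex, at 2.65, Tm4sf1, a membrane protein of endothelium and carcinomas, at 2.59, Gsta4, a glutathione transferase, at 2.31 and Gpa33, an intestinal surface antigen, at 2.27. None of these passed: edgeR's quasi-likelihood test with Benjamini-Hochberg called 0 of 14085 genes. The smallest adjusted p in edgeR was 0.0916 for H2-T-ps, and 1427 genes had an unadjusted p under 0.05 where chance gives 704. DESeq2 called 86 genes, limma voom called 1 and limma trend called 0. Without JQ1 replicate 2 the count was 17, and it was 1 without vehicle replicate 1, JQ1 replicate 1, combination replicate 1 or combination replicate 2. With no filter on low counts it was 250, and with only the vehicle and JQ1 libraries in the fit it was 1.

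Among gene lists, 5 were higher and 6 lower with JQ1 alone by camera at the preset correlation. The histone list had a median log2 fold change of −0.83, with 10 of 11 tested members negative (camera adjusted p = 2.83e-05; adjusted p = 0.481 with an estimated correlation). None of its members passed over all genes and 6 fell when adjusted over the list alone, the lead being Hist1h4h at −1.18 (SE 0.24) and Hist1h2bg at −1.36 (SE 0.32). Histone genes are near-identical paralogs, so counts of single members are uncertain, and how shared reads were counted is not given in the sources used here. Endothelial markers had a median of 0.60, with Flt1, a VEGF receptor, at 1.03 and Pecam1 at 1.30 (adjusted p = 0.000204; adjusted p = 0.742 with an estimated correlation), and airway markers a median of 1.66, with the mucin Muc5b at 4.11 and the club cell secretoglobin Scgb1a1 at 3.51 (0.00177; adjusted p = 0.742 with an estimated correlation). Alveolar type 2 markers had a median of −0.59, with Hc at −2.15 and the lineage factor Nkx2-1 at −0.78, although Napsa was at 1.01. MHC class II genes had a median of −0.63, with H2-Aa at −2.77 (SE 0.67) and the invariant chain Cd74 at −1.75. The response genes of type I interferon had a median of 0.91, with Oasl1 at 3.50 and Irf7 at 2.62, and those of interferon gamma 0.94, with Iigp1 at 2.39. Neutrophil markers had a median of 1.20, led by S100a8 at 3.0, while mitosis genes, with Plk1 at −1.70, alveolar macrophage markers and ribosomal protein genes had medians of −0.48, −0.31 and −0.29. For these last 8 lists the camera adjusted p lay between 0.00583 and 0.0388, and the lowest adjusted p = 0.742 with an estimated correlation. Adjusted over the list alone, 1 airway gene rose and 1 gene each of the alveolar type 2 and MHC class II lists fell. Several of these medians came mostly from a single library. Against the vehicle mean, JQ1 replicates 1 and 2 had medians of 2.23 and 0.037 for airway, 1.32 and 0.20 for neutrophil, 1.16 and 0.24 for interferon gamma, 1.05 and 0.11 for type I interferon and −0.20 and −1.75 for MHC class II genes. For endothelium they were 0.74 and 0.43, with vehicle replicates 1 and 2 at −0.33 and 0.33, and for histones −0.67 and −1.03. With a sex term 6 lists passed, 1 of them, heat shock, new, and the calls of the airway, MHC class II, neutrophil, mitosis, alveolar macrophage and ribosomal protein lists ended. Calls also ended without JQ1 replicate 1 for airway, neutrophil, alveolar macrophage and both interferon lists, and without JQ1 replicate 2 for MHC class II, mitosis, ribosomal protein, alveolar macrophage and alveolar type 2. Without vehicle replicate 1 they ended for endothelium, ribosomal protein, alveolar macrophage and alveolar type 2, and without vehicle replicate 2 for neutrophil, mitosis and alveolar macrophage.

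DNA replication genes stood at a median of 0.056 with JQ1 alone, and their summed expression was 265 ± 108 CPM (n = 2) against 258 ± 31.1 CPM (n = 2) in vehicle. The whole replication-dependent histone cluster family, 57 tested genes, summed to 1345 ± 378 CPM with JQ1 and 2878 ± 250 CPM in vehicle, with 54 of 57 negative and a median of −1.06. The ribosomal RNA share of the JQ1 libraries, 32.1% ± 5.13 against 23.4% ± 1.38, moved with these groups.

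Anti-PD-1 against vehicle shows the antibody alone. Among the genes with the smallest p, none of which passed the test, Pdk4, which restrains pyruvate dehydrogenase, was at 34.5 ± 31.1 CPM (n = 2) against 3.95 ± 0.505 CPM (n = 2). The chemokine Cxcl12 was at 61.1 ± 4.75 against 22.1 ± 7.42 CPM, the kinase Tnik at a log2 fold change of 1.66 and the adhesion gene Nrxn2 at 3.56. Lower were the transcription factor Tfap2b, with 3 counts against 585, a ratio of 159 (95% counting interval 54.3 to 776), the monooxygenase-like gene Moxd1 at −2.85 (SE 0.51), Fam25c at −1.97, Trim6 at −1.73 and the catenin Ctnnd2 at −1.29. edgeR's quasi-likelihood test with Benjamini-Hochberg called 0 genes, with an adjusted p of 1 for each of them, and 278 genes had an unadjusted p under 0.05 where chance gives 704. DESeq2 called 11, limma voom called 0, limma trend called 0, and edgeR with no filter on low counts called 55. Without vehicle replicate 1 the count was 1.

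T cell transcripts were near the floor in every group, so the antibody's target cells were barely measured. With probe capture this need not mean few T cells. Over the 8 libraries Pdcd1, which encodes PD-1, had 8 counts, Cd8a 6, Cd4 25, the regulatory T cell factor Foxp3 15, the checkpoint receptor Ctla4 44, Gzmb 1 and Ifng 0. Of the 44 Ctla4 counts, 25 were in anti-PD-1 replicate 1, and its mean was 1.20 ± 0.770 CPM (n = 2) with the antibody against 0.0861 ± 0.122 CPM (n = 2) in vehicle. Cd4 was at 0.537 ± 0.228 against 0.191 ± 0.0543 CPM. The 22 T cell markers, 5 of them tested, summed to 21.8 ± 5.7 CPM with the antibody, 17.4 ± 1.5 in vehicle, 17.9 ± 11.2 with JQ1 and 10 ± 2.2 CPM with the combination. The lower combination sum rests on Bcl11b and Tcf7, at 5.99 and 7.51 CPM in vehicle and 0.21 and 3.07 in the combination. Cd274, which encodes the PD-1 ligand, differed from vehicle by −0.05 (SE 0.64) with the antibody, 0.04 with JQ1 and 0.10 with the combination.

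Lists of vessel and stroma markers had higher medians with the antibody, with no member called over all genes. The list of endothelial genes had 20 of 22 members positive and a median of 0.49, with Ramp2 at 1.07 (SE 0.33) and Tmem100 at 1.65 (camera adjusted p = 3.09e-07; adjusted p = 0.669 with an estimated correlation). Fibroblast and matrix genes had 19 of 21 positive and a median of 0.27, with the proteoglycan Dcn at 1.80, Fbln1 at 2.17 and Col3a1 at 1.09 (5.47e-06; adjusted p = 0.669 with an estimated correlation). Circadian clock genes had a median of 0.42, with Hlf at 3.43, and airway markers one of 1.02, with Scgb1a1 at 3.62 (both 6.92e-05; adjusted p = 0.669 with an estimated correlation). Genes of cholesterol synthesis had a median of −0.35, with 19 of 21 negative and the mevalonate kinase Mvk at −1.15 (0.00053; adjusted p = 0.669 with an estimated correlation). MAPK output genes had a median of −0.21 and glycolysis genes −0.16, with Egln3 at −2.03, while striated muscle, T cell and ribosomal protein genes had medians of 1.09, 0.37 and 0.19. Those 5 lists had camera adjusted p of 0.00388 to 0.0323, and the lowest adjusted p = 0.669 with an estimated correlation. No member of these 10 lists passed over all genes. Adjusted over the list alone, 2 clock genes and 1 gene each of the airway, striated muscle and T cell lists rose. Against the vehicle mean, anti-PD-1 replicates 1 and 2 had medians of 1.7 and −0.54 for striated muscle, −0.027 and 0.35 for ribosomal protein, 1.2 and 0.46 for airway and 0.47 and 0.22 for fibroblast and matrix genes. For endothelium they were 0.43 and 0.48, but vehicle replicates 1 and 2 were themselves at −0.33 and 0.33. In anti-PD-1 replicate 2, 8 of the 21 fibroblast and matrix genes were above both vehicle libraries and 9 below both. Calls ended without vehicle replicate 1 for endothelium, T cell, glycolysis and MAPK output, and without anti-PD-1 replicate 1 for fibroblast and matrix, T cell, striated muscle and glycolysis. They ended without anti-PD-1 replicate 2 for cholesterol synthesis, MAPK output and ribosomal protein, without vehicle replicate 2 for ribosomal protein, and with a sex term for ribosomal protein and glycolysis, while 16 lists passed. The T cell call ended without JQ1 replicate 1, JQ1 replicate 2, combination replicate 1 or combination replicate 2, and the ribosomal protein call without JQ1 replicate 2. The direction of the test turned without anti-PD-1 replicate 1 for T cell and striated muscle, and for ribosomal protein without anti-PD-1 replicate 2 or vehicle replicate 2. With no filter on low counts 18 lists passed.

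The combination against vehicle shows both treatments together, and 676 of 14085 genes were called. Scgb1a1 (chromosome 19, 9083636 to 9087958), the secretoglobin of club cells, rose by 5.96 on the log2 scale (SE 0.89), to 275 ± 43.2 CPM (n = 2) from 4.42 ± 1.31 CPM (n = 2). Sox2 (chromosome 3, 34650405 to 34652461), a transcription factor of airway epithelium and stem cells, rose with 211 counts against 3, a ratio of 254 (95% counting interval 85.8 to 1240), or 403 without combination replicate 2, and its 3 vehicle counts were all in vehicle replicate 2. Gfra1, a GDNF receptor, rose by 7.82 (SE 1.22) and Iigp1, an interferon-induced GTPase, by 5.20 (SE 0.99). Mycn (chromosome 12, 12936093 to 12941914), a MYC family oncogene, fell by 4.57 (SE 0.78), from 53.8 ± 11.7 to 2.85 ± 3.11 CPM. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg were 0.0244, 0.0447, 0.0252, 0.0327 and 0.0276. Combination replicates 1 and 2 held 49 and 366 counts of Gfra1 and 13 and 207 of Iigp1. Without combination replicate 2, Gfra1, Iigp1 and Mycn were at 6.79, 3.28 and −3.43. Without combination replicate 1, Iigp1 and Mycn were at 5.93 and −6.33, and Gfra1 was at 6.68 without vehicle replicate 2 and has no finite size without vehicle replicate 1, which held all 5 of its vehicle counts. With the ribosomal RNA share as a term Gfra1, Iigp1 and Mycn turned direction, to −0.41, −2.29 and 0.50. Of 70 called results of named genes in this contrast, the call was kept by 0 without vehicle replicate 2, 2 without vehicle replicate 1, 1 without combination replicate 2, 56 without combination replicate 1, 42 without either of the anti-PD-1 libraries and 66 without either of the JQ1 libraries. None of them turned direction with a library left out.

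Other genes with large rises were the lipocalin Apod (4.45), the glucocorticoid-responsive factor Klf15 (4.17), Eps8l3 (3.56), the clock repressor Ciart (3.51), the syntenin Sdcbp2 (3.21) and the small GTPase Arl4d (3.20), with SE from 0.47 to 1.0. Falls were led by Moxd1, at a ratio of 64.5 (counting interval 17.7 to 534), the histone genes Hist1h2ae, 62 (11 to 2460), and Hist1h2ag, 33.9 (9.28 to 281), the T cell and neuronal factor Bcl11b, 52.3 (9.27 to 2080), the G protein regulator Rgs16, 35.4 (12.0 to 172), and the heart antisense RNA Mhrt, 30.7 (8.40 to 255). Also lower was the secretory granule gene Scg5, at a ratio of 27.1 (4.75 to 1080). Mhrt lies antisense to a myosin gene, and reads of the pair cannot be told apart without strand. Acoxl, an acyl-CoA oxidase-like gene, fell by 4.58 and Hist1h3b by 4.44 on the log2 scale. The largest adjusted p among these genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg, was 0.0409. Combination replicate 2 carried several of the rises, with 330 counts of Klf15 against 27 in combination replicate 1, 99 against 7 of Ciart and 96 against 9 of Arl4d. Without it Klf15 was at 2.58, Ciart at 1.71 and Arl4d at 1.74, and without combination replicate 1 they were at 4.86, 4.20 and 3.83, with Apod at 3.86. Arl4d was at 4.11 without vehicle replicate 1 and 2.58 without vehicle replicate 2. In combination replicate 1, Moxd1, Hist1h2ae, Hist1h2ag, Hist1h3b, Mhrt and Scg5 had 0 counts, in combination replicate 2 Bcl11b had 0, and Rgs16 had 2 and 1. Klf15 and Arl4d turned direction with the ribosomal RNA share as a term, to −1.11 and −1.75.

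**Figure D3:**
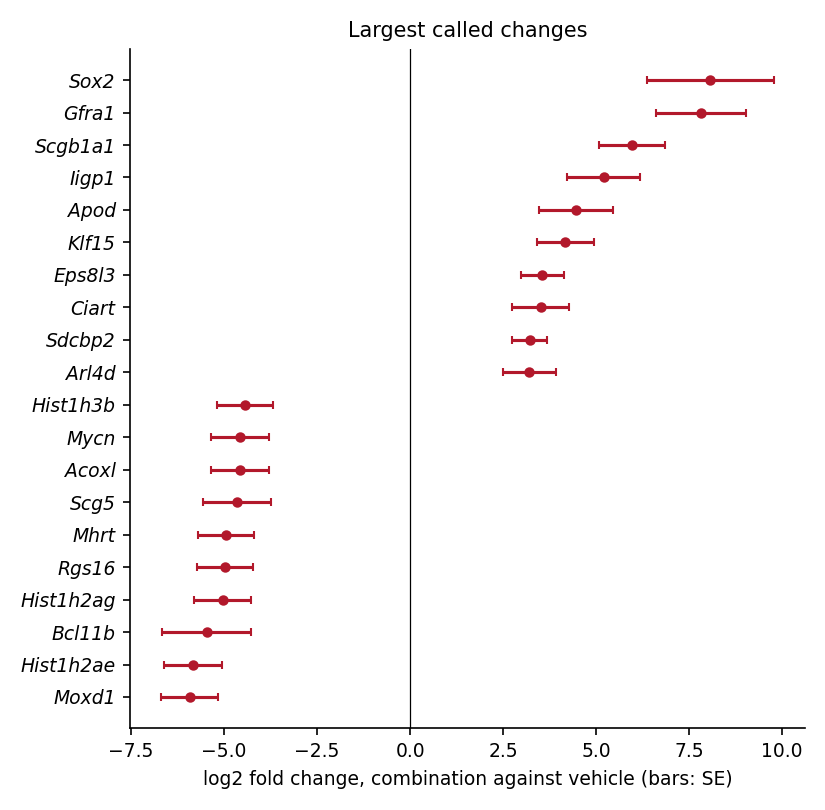
Fitted log2 fold changes in the combination against vehicle (n = 2 libraries each) for the 10 largest called rises and 10 largest called falls, with bars of 1 SE. Scgb1a1 is at 5.96 (SE 0.89) and Mycn at −4.57 (SE 0.78), and fitted values of genes with 1 to 3 counts on a side depend on the prior count.

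Of the 676 genes, 344 rose and 332 fell, 3845 genes had an unadjusted p under 0.05, and DESeq2 called 1665. The split was 408 to 242 with upper-quartile factors and 292 to 560 with limma trend, which moved the median of all genes from 0.07 to −0.06. The count depended on single libraries: it was 7 without vehicle replicate 2, 19 without vehicle replicate 1, 15 without combination replicate 2, 1115 without combination replicate 1, 308 without anti-PD-1 replicate 1 and 291 without anti-PD-1 replicate 2. It was 339 with a sex term, 245 with only the vehicle and combination libraries in the fit, 1992 with no filter on low counts and 0 with the ribosomal RNA share as a term.

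Histones and cell cycle genes were lower in the combination. In the histone list 6 of 11 genes fell, 0 rose and 5 did not pass, against 7 that fell adjusted over the list alone, with a median of −1.38 and Hist1h2ac at −2.67 (SE 0.41) and H2afx at −2.37 (SE 0.40) among them (camera adjusted p = 5.4e-07; adjusted p = 0.267 with an estimated correlation). Over the 57 genes of the histone cluster family, 36 fell and 0 rose, with a median of −2.44, or −2.41 with genes at 0 counts set at their bound, and their sum was 731 ± 202 CPM (n = 2) against 2878 ± 250 CPM (n = 2). In the DNA replication list Mcm2, a subunit of the replicative helicase, fell by 2.75 (SE 0.45) and 26 members did not pass, against 5 that fell adjusted over the list alone, with a median of −1.09 (5.91e-05; adjusted p = 0.606 with an estimated correlation). The mitosis list had a median of −1.23, with falls of the kinase Plk1 by 3.61 and the kinesin Kif23 by 2.42 and 21 members not passing, against 4 falls adjusted over the list alone (0.000182; adjusted p = 0.677 with an estimated correlation). Nop56 and Rrp9, of ribosome biogenesis, fell by 2.05 and 2.15 in a list with a median of −0.64, 24 members not passing and 3 falls adjusted over the list alone (0.00292; adjusted p = 0.606 with an estimated correlation). Without combination replicate 1 Nop56 was at −2.70, and without combination replicate 2 Rrp9 was at −2.94. Against the vehicle mean, combination replicates 1 and 2 had medians of −1.64 and −1.57 for histones, −0.69 and −1.23 for DNA replication, −1.69 and −0.68 for mitosis and −0.47 and −0.60 for ribosome biogenesis. The proliferation marker Mki67 was at −1.07 (SE 0.51) and did not pass. These groups moved with the ribosomal RNA share of the libraries, 49.9% ± 4.67 against 23.4% ± 1.38.

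**Figure D4:**
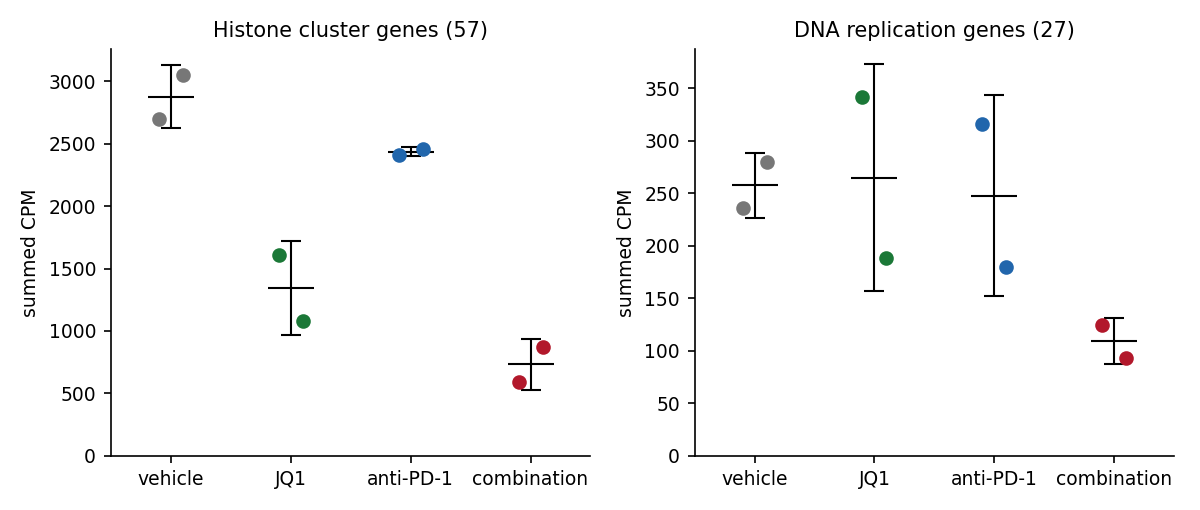
Summed CPM of the histone cluster family and of the DNA replication genes with a point for each of the 8 libraries and group mean and SD as lines. Histone sums are 2878, 1345, 2438 and 731 CPM in vehicle, JQ1, anti-PD-1 and combination, and replication sums are 258, 265, 248 and 109 CPM.

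Transcriptional readouts of MAPK signalling were lower in the combination. Phlda1, Etv5, Hbegf and Epha4 of the MAPK output list fell by 2.22, 1.89, 1.82 and 1.62 on the log2 scale. In that list 13 of 17 members did not pass, and adjusted over the list alone 10 fell and 1 rose (median −1.06; camera adjusted p = 5.91e-05; adjusted p = 0.606 with an estimated correlation). Genes of the mesenchymal transition had a median of −0.64, with falls of Tgfbi by 1.81 and vimentin, Vim, by 1.27, and 12 not passing, against 4 falls adjusted over the list alone (0.0126; adjusted p = 0.636 with an estimated correlation). Heat shock genes had a median of −0.72, with none past the test over all genes and 4 falls adjusted over the list alone (0.0104; adjusted p = 0.635 with an estimated correlation). Of the striated muscle genes the heart myosin Myh6 fell by 2.18 and 4 did not pass, also adjusted over the list alone (median −1.38; 0.0239; adjusted p = 0.606 with an estimated correlation). Without combination replicate 1, Phlda1, Etv5 and Myh6 were at −2.85, −2.64 and −2.81. Against the vehicle mean, combination replicates 1 and 2 had medians of −0.94 and −1.12 for MAPK output, −1.05 and −0.23 for mesenchymal transition, −0.16 and −1.16 for heat shock and −0.71 and −1.2 for striated muscle. The heat shock call ended without vehicle replicate 2 or combination replicate 2, the mesenchymal transition call without combination replicate 1, and the striated muscle call without combination replicate 1 or combination replicate 2, with limma voom or with a sex term. With the ribosomal RNA share as a term Epha4 turned direction, to 0.79. The same libraries held 49.9% ± 4.67 ribosomal RNA.

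Lists of antioxidant defence, the clock, interferon and cholesterol synthesis had higher medians in the combination, most of them with a larger value in combination replicate 2. The NRF2 targets Slc7a11, the cystine transporter, Txnrd1, G6pdx and Gclc rose by 2.43, 1.57, 1.53 and 1.26, with 10 of 14 not passing and 10 rises adjusted over the list alone (median 1.45; camera adjusted p = 8.65e-05; adjusted p = 0.606 with an estimated correlation). The clock genes Ciart, Per3, Tef and Per2 rose by 3.51, 2.51, 1.83 and 1.69, with 13 of 17 not passing and 11 rises adjusted over the list alone (median 1.37; 1.26e-05; adjusted p = 0.606 with an estimated correlation). Iigp1, Igtp and Gbp2, GTPases induced by interferon gamma, rose by 5.20, 3.24 and 2.28, with 10 of 13 not passing and 5 rises adjusted over the list alone (median 1.81; 0.000178; adjusted p = 0.606 with an estimated correlation). No gene of the type I interferon list passed, in either adjustment, with all 15 positive and a median of 1.04 (0.0127; adjusted p = 0.606 with an estimated correlation). Squalene epoxidase, Sqle, and Acat2 rose by 2.03 and 1.99 in cholesterol synthesis, with 19 of 21 not passing and 4 rises adjusted over the list alone (median 0.86; 0.0179; adjusted p = 0.69 with an estimated correlation). Trp53inp1 and Perp rose by 2.69 and 2.21 among p53 targets, with 16 of 18 not passing, and adjusted over the list alone 8 rose and 1 fell (median 0.99; 0.00643; adjusted p = 0.606 with an estimated correlation). In oxidative phosphorylation Cox7a2 rose by 1.88 and 25 of 26 did not pass, and adjusted over the list alone 6 rose and 1 fell (median 0.67; 0.0438; adjusted p = 0.86 with an estimated correlation). Combination replicates 1 and 2 had medians against the vehicle mean of 1.05 and 1.21 for NRF2 targets, 0.82 and 1.56 for the clock, 0.72 and 1.89 for interferon gamma, 0.39 and 0.96 for type I interferon, 0.53 and 0.86 for cholesterol synthesis, 0.59 and 1.22 for p53 targets and 0.058 and 0.96 for oxidative phosphorylation. Summed CPM were 432.5 ± 162.8 against 381.3 ± 21.9 in vehicle for cholesterol synthesis, and 1303 ± 402 against 1297 for oxidative phosphorylation (n = 2 each). Calls of both interferon lists, cholesterol synthesis, p53 targets and oxidative phosphorylation ended without combination replicate 2, where the test of the last turned direction, and oxidative phosphorylation also without vehicle replicate 2 or with a sex term. Without combination replicate 2, Ciart was at 1.71, Iigp1 at 3.28, Igtp at 2.21, Gbp2 at 1.66, Sqle at 1.04, Acat2 at 1.38, Trp53inp1 at 1.84, Cox7a2 at 1.23 and Slc7a11 at 3.04. Without combination replicate 1, Slc7a11 was at 1.31, Ciart at 4.20 and Iigp1 at 5.93, and Igtp was at 2.63 without vehicle replicate 1 and 4.38 without vehicle replicate 2. Iigp1, Gbp2 and Sqle turned direction with the ribosomal RNA share as a term, to −2.29, −2.49 and −0.84. The ribosomal RNA share, 49.9% ± 4.67, moved with these groups as well.

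Markers of cell types went in different directions in the combination. Endothelial genes had a median of 0.89, with rises of Pecam1 by 1.74 and Flt1 by 1.15 and 20 of 22 not passing, against 6 rises adjusted over the list alone (camera adjusted p = 0.000143; adjusted p = 0.606 with an estimated correlation). Airway genes had a median of 2.64, with Scgb1a1 called in both adjustments and 12 of 13 not passing (0.0109; adjusted p = 0.69 with an estimated correlation). Among alveolar type 2 markers Napsa and S100g rose by 1.42 and 1.98 and Nkx2-1 and Etv5 fell by 1.63 and 1.89, with 13 not passing and the same counts adjusted over the list alone. Surfactant protein C, Sftpc, which did not pass, was at 2630 ± 885 CPM (n = 2) against 1770 ± 868 CPM (n = 2). Among fibroblast and matrix genes Dcn, Inmt and Pdgfra rose by 2.58, 2.22 and 2.02 while collagen Col1a1 fell by 1.92, with 17 of 21 not passing, and adjusted over the list alone 3 rose and 3 fell. The smooth muscle actin Acta2 fell by 2.44 and the pericyte gene Rgs5 rose by 1.49, with 8 of 10 not passing, and adjusted over the list alone 1 rose and 2 fell. By camera the last 3 lists had an adjusted p of 0.723, 0.723 and 0.65, and in the fibroblast and matrix list the signs of the median, the mean and the test were not all the same. Combination replicates 1 and 2 had medians against the vehicle mean of 2.03 and 0.061 for airway genes, so that median rests on combination replicate 1, and of 0.72 and 0.85 for endothelium, with vehicle replicates 1 and 2 at −0.33 and 0.33. The airway call ended without combination replicate 1, with limma voom or with a sex term. Without vehicle replicate 2, S100g, Inmt and Pdgfra were at 2.68, 2.86 and 2.85. Without combination replicate 1, Nkx2-1 and Etv5 were at −2.27 and −2.64, and without combination replicate 2, Acta2 was at −3.14. Napsa and Dcn turned direction with the ribosomal RNA share as a term, to −0.86 and −0.45. Ribosomal RNA was 49.9% ± 4.67 of these libraries.

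**Figure D5:**
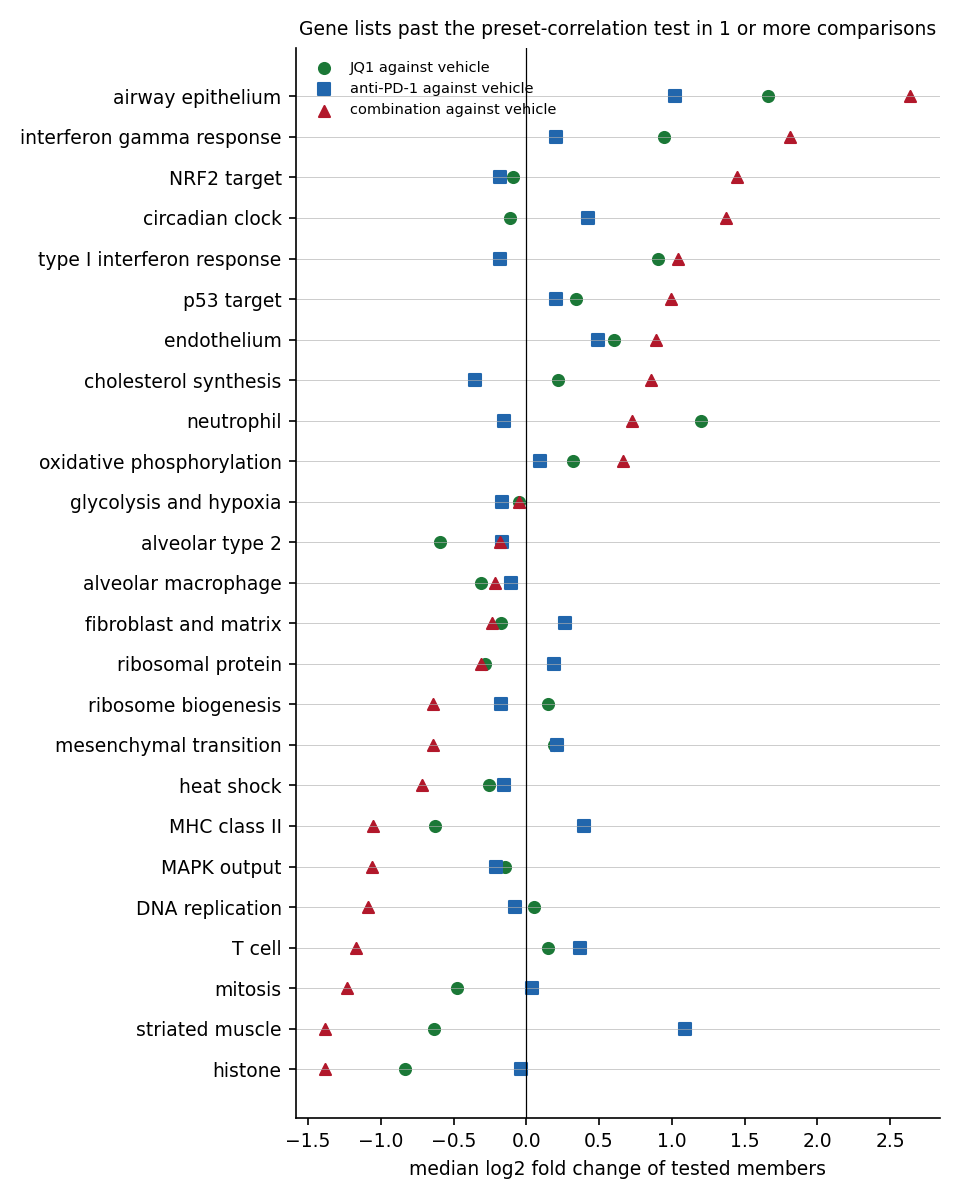
Median log2 fold change of the members of each gene list past the camera test at the preset correlation in 1 or more of JQ1, anti-PD-1 and the combination against vehicle, with a marker for each. In the combination against vehicle the histone list is at −1.38 and the airway list at 2.64, and no list passes with an estimated correlation.

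Genes tied to the drug target and tumour model were measured throughout. Against vehicle in the combination, Brd2 was at −0.70 (SE 0.25), Brd3 at 0.18, Hexim1, a P-TEFb inhibitor, at −1.15 (SE 0.47), Myc at −0.67 (SE 0.38) and Trp53 at 0.42 (SE 0.53), and none passed. With JQ1 alone they were at −0.67, 0.32, −0.63, 0.44 and 0.58 in the same order. With the antibody alone they were at 0.28, −0.14, 0.26, −0.01 and −0.16, and Myc was at 0.00 with RLE factors. The list of genes that BET inhibitors induce had a median of −0.97 in the combination (camera adjusted p = 0.214), with a fall of Hist1h2bc by 1.38, 5 of 6 not passing, and 1 rise and 2 falls adjusted over the list alone. The list of genes they repress had a median of 0.10 (0.723), with Mycn fallen, 8 of 9 not passing, and 1 rise and 1 fall adjusted over the list alone, and its median and mean or test differed in sign.

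The combination against JQ1 shows what the antibody adds in the presence of the inhibitor. Prdx6 (chromosome 1, 161240112 to 161251219), a peroxiredoxin, rose by 2.7 (SE 0.31), to 632 ± 189 CPM (n = 2) from 97.4 ± 14.9 CPM (n = 2). The clock gene Per3 (chromosome 4, 151003652 to 151044665) rose by 2.78 (SE 0.34) and Id2 (chromosome 12, 25093799 to 25097140), an inhibitor of bHLH factors, fell by 2.12 (SE 0.27). By edgeR's quasi-likelihood test with Benjamini-Hochberg their adjusted p were 0.0431, 0.0431 and 0.0477, and no other of the 14085 genes passed, while 1987 had an unadjusted p under 0.05. Next in p, and not past the threshold, were Fmo2, a monooxygenase of the lung, at 2.34, the clock output factor Tef at 2.08 and Ccdc141 at 1.96, and on the other side Mcm2 at −2.81, the tubulins Tubb5 and Tuba1a at −2.09 and −2.02, and the protease Adamts9 at −2.01. Counts of called genes were 417 with DESeq2, 5 with limma voom, 8 with limma trend, 672 with no filter on low counts, 6 with GC and length trends removed, 5 with libraries thinned to equal totals, 26 thinned to equal protein-coding counts, 2 with RLE, upper-quartile factors or protein-coding genes only, 1 with the ribosomal RNA share as a term, and 0 with a sex term or with only the libraries compared. The count was 114 without combination replicate 1, 20 without JQ1 replicate 1, 2 without JQ1 replicate 2, 1 without combination replicate 2, and 0 without either vehicle replicate 1, vehicle replicate 2, anti-PD-1 replicate 1 or anti-PD-1 replicate 2.

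The combination against anti-PD-1 shows what JQ1 adds in the presence of the antibody. Gfra1 rose by 5.95 (SE 1.07), to 40.5 ± 28.1 CPM (n = 2) from 0.618 ± 0.608 CPM (n = 2), Iigp1 by 4.82, the acute phase protein Orm1 by 3.99, the Golgi calcium pump Atp2c2 by 3.95 and the metalloprotease Adam28 by 3.73. Mycn fell by 4.67 (SE 0.78), to 2.85 ± 3.11 from 57.7 ± 22.1 CPM, and the glutamate transporter Slc1a3 by 4.69, while Bcl11b, Hist1h2ae and Mhrt fell at ratios of 46.3 (counting interval 8.18 to 1840), 34.8 (6.12 to 1390) and 29.1 (7.93 to 242). Without anti-PD-1 replicate 2, which held 746 counts of Slc1a3 against 174 in anti-PD-1 replicate 1, Slc1a3 was at −2.96, Gfra1 at 5.26 and Iigp1 at 5.81. Without anti-PD-1 replicate 1, Slc1a3, Iigp1 and Adam28 were at −5.48, 4.15 and 4.64, and Gfra1 had 2 counts left on that side. Without combination replicate 2, Gfra1, Iigp1, Orm1 and Adam28 were at 4.95, 2.88, 2.3 and 3.13, and Mycn at −3.54, and Slc1a3 had 2 counts left on that side. Without combination replicate 1, Iigp1, Orm1 and Atp2c2 were at 5.56, 4.69 and 3.31, and Mycn at −6.43. Hist1h2ae and Mhrt had 0 counts in combination replicate 1 and Bcl11b 0 in combination replicate 2. With the ribosomal RNA share as a term, Gfra1, Iigp1, Orm1, Adam28 and Mycn turned direction. Of 10 called results of named genes in this contrast, the call was kept by 1 without anti-PD-1 replicate 1, 0 without anti-PD-1 replicate 2, 1 without combination replicate 2, 9 without combination replicate 1, 5 without vehicle replicate 1 and 4 without vehicle replicate 2. Of the 57 histone cluster genes 34 fell and 0 rose, with a median of −2.28. By edgeR's quasi-likelihood test with Benjamini-Hochberg 303 genes rose and 293 fell, 596 in all, and 3798 had an unadjusted p under 0.05. The split was 361 to 200 with upper-quartile factors, 279 to 531 with limma trend and 615 to 979 with DESeq2, and the count was 1920 with no filter on low counts, 212 with a sex term, 57 with only the libraries compared and 0 with the ribosomal RNA share as a term. It was 3 without anti-PD-1 replicate 1, 18 without anti-PD-1 replicate 2, 20 without combination replicate 2, 967 without combination replicate 1, 89 without vehicle replicate 1 and 70 without vehicle replicate 2.

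The JQ1 effect over both backgrounds sets the 4 libraries with the inhibitor against the 4 without it. Among the rises were the intestinal mucin Muc3, with 275 counts against 2, a ratio of 259 (95% counting interval 71.0 to 2150), the sulfotransferase Sult1d1, at a ratio of 156 (42.6 to 1300), Dpcr1, by 4.45, and the keratin Krt20, by 4.40 (SE 0.94), to 28.4 ± 26.2 CPM (n = 4) from 1.34 ± 1.02 CPM (n = 4). JQ1 replicate 1 held 229 of the Muc3 counts, 570 counts of Dpcr1 against 52 in JQ1 replicate 2, and 621 of Krt20 against 74, and combination replicate 2 held 120 of the 166 Sult1d1 counts. Without JQ1 replicate 1 the Muc3 ratio was 64.1 and Dpcr1 and Krt20 were at 3.02 and 3.14, and the Sult1d1 ratio was 54.6 without combination replicate 2 and 253 without JQ1 replicate 2. The mucin-type glycosyltransferase Gcnt3 rose by 3.39. The list of gut-like differentiation genes had a median of −0.36 in this contrast (camera adjusted p = 0.892), with none of 11 called, also adjusted over the list alone, and the signs of its median, mean and test were not all the same. Rises also included Iigp1 (3.61), the serine palmitoyltransferase subunit Sptssb (3.60), Eps8l3 (3.50), Rab11fip4 (2.98) and Bcas1 (2.92). JQ1 replicate 1 held 237 counts of Sptssb and 252 of Bcas1, against 24 and 27 in JQ1 replicate 2, and without it they were at 2.23 and 1.60. Combination replicate 2 held 207 counts of Iigp1, and without it Iigp1 and Rab11fip4 were at 2.64 and 2.09. Anti-PD-1 replicates 1 and 2 had 2 and 7 counts of Sptssb and 3 and 27 of Krt20, and both counts of Muc3 on the other side were in anti-PD-1 replicate 1. Among falls were the MHC class II chain H2-Aa by 2.74 (SE 0.47), to 39.3 ± 28.8 from 264 ± 61.7 CPM, and Mycn by 2.76. Falls also included the adhesion gene Ntm by 3.51, Rgs16 by 3.25, the potassium channel Kcnk2 by 3.15, Slc1a3 by 3.07, Kcnip4 by 2.78, the histone genes Hist1h2bk and Hist1h2bm by 2.7 and 2.59, and the anion exchanger Slc26a4 by 2.52. Without combination replicate 2 H2-Aa was at −3.48, without JQ1 replicate 1 Slc26a4 was at −3.40, without combination replicate 1 Mycn was at −3.65, and without anti-PD-1 replicate 2 Slc1a3 was at −2.21. Some falls rest on few counts in libraries with JQ1, and no value is given without 1 of these: JQ1 replicates 1 and 2 and combination replicates 1 and 2 held 8, 1, 0 and 2 counts of Ntm, 10, 1, 0 and 19 of Kcnk2, 1, 15, 2 and 1 of Kcnip4, and 63, 49, 1 and 23 of Hist1h2bk. With the ribosomal RNA share as a term, Muc3, Sult1d1, Dpcr1, Krt20, Iigp1, Sptssb, Bcas1, Mycn and Kcnip4 turned direction. Of 77 called results of named genes in this contrast, the call was kept by 4 without vehicle replicate 2, 10 without vehicle replicate 1, 16 without anti-PD-1 replicate 1, 18 without anti-PD-1 replicate 2, 32 without combination replicate 2, 44 without either of the JQ1 libraries and 60 without combination replicate 1. Brd2, a JQ1 target, fell by 0.82 (SE 0.18; adjusted p = 0.0291 by edgeR's quasi-likelihood test). Hexim1, at −1.02, did not pass (same test, 0.0722).

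In all 595 genes rose and 571 fell, 1166 together, with 4458 at an unadjusted p under 0.05. The split was 812 to 361 with upper-quartile factors, 408 to 696 with limma trend and 824 to 1334 with DESeq2, and the count was 2527 with no filter on low counts, 572 in a 2-group fit, 700 with libraries thinned to equal protein-coding counts and 0 with the ribosomal RNA share as a term. Leaving out single libraries gave 17 without vehicle replicate 2, 62 without vehicle replicate 1, 497 without JQ1 replicate 1, 466 without JQ1 replicate 2, 143 without anti-PD-1 replicate 1, 129 without anti-PD-1 replicate 2, 432 without combination replicate 2 and 1716 without combination replicate 1.

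Histones led the lists for JQ1 over both backgrounds. Of 11 genes 7 fell, 0 rose and 4 did not pass, with the same 7 adjusted over the list alone, a median of −1.29 and Hist1h4h at −1.37 (SE 0.17) and Hist1h4i at −2.10 (camera adjusted p = 2.52e-07; adjusted p = 0.202 with an estimated correlation). In the histone cluster family 40 of 57 fell, with a median of −1.65. Interferon gamma genes (median 1.40) and NRF2 targets (median 0.88), the latter with rises of the sulfiredoxin Srxn1 by 1.71 and Tkt by 1.06, had 3 of 13 and 4 of 14 members risen, and 6 and 7 adjusted over the list alone. Tkt turned direction with the ribosomal RNA share as a term, to −0.31. The averages differ between backgrounds: with JQ1 alone and with JQ1 on the antibody the medians were −0.088 and 1.66 for NRF2 targets, 0.056 and −1.24 for DNA replication and 0.19 and −0.84 for mesenchymal transition, which have opposite signs. They were 0.94 and 1.53 for interferon gamma, 0.91 and 1.26 for type I interferon, 0.22 and 1.39 for cholesterol synthesis, 0.60 and 0.36 for endothelium, 1.66 and 0.38 for airway, −0.83 and −1.40 for histones, −0.48 and −1.34 for mitosis, −0.63 and −2.46 for striated muscle, −0.63 and −1.35 for MHC class II, −0.29 and −0.41 for ribosomal protein, −0.26 and −0.58 for heat shock and −0.14 and −0.74 for MAPK output. Mitosis genes had a median of −0.73 with 2 of 23 fallen, and 5 adjusted over the list alone, and all 3 lists had a camera adjusted p = 0.00127, against adjusted p = 0.697 with an estimated correlation. Type I interferon (median 1.30), cholesterol synthesis (0.90), endothelium (0.43) and airway (1.67) were higher, with 0, 2, 4 and 1 members risen and 0, 6, 6 and 2 adjusted over the list alone. Among the endothelial members was Cldn5, of tight junctions, which rose by 1.70. Striated muscle (−1.54), MHC class II (−0.98), ribosomal protein (−0.37), mesenchymal transition (−0.40), DNA replication (−0.56), heat shock (−0.60) and MAPK output (−0.35) were lower, with 2, 1, 2, 3, 1, 1 and 4 members fallen and 2, 2, 2, 4, 4, 2 and 6 adjusted over the list alone. In the MAPK list Fosl1, an AP-1 subunit, rose by 2.98. For these 11 lists the camera adjusted p ran from 0.00207 to 0.0217, and the lowest adjusted p = 0.697 with an estimated correlation. Calls ended without JQ1 replicate 1 for airway and MAPK output, without JQ1 replicate 2 for DNA replication, heat shock and mesenchymal transition, without combination replicate 1 for airway and ribosomal protein, and without combination replicate 2 for DNA replication, cholesterol synthesis, heat shock and MAPK output. They ended without anti-PD-1 replicate 1 for mitosis and DNA replication, without anti-PD-1 replicate 2 for ribosomal protein, without vehicle replicate 1 for endothelium, without vehicle replicate 2 for heat shock, and with limma voom or a sex term for airway. Ribosomal RNA was 32.1% ± 5.13 and 49.9% ± 4.67 in the groups with JQ1 and 23.4% ± 1.38 and 24.4% ± 0.506 in those without.

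The anti-PD-1 effect over both backgrounds sets the 4 libraries with the antibody against the 4 without it. Id2 fell by 1.54 (SE 0.19), to 142 ± 96.6 CPM (n = 4) from 345 ± 114 CPM (n = 4), and Moxd1 by 3.83 (SE 0.47), to 1.09 ± 1.15 from 10.7 ± 5.80 CPM, with an adjusted p of 0.0498 for both by edgeR's quasi-likelihood test with Benjamini-Hochberg. Next in p, not past the threshold, were Per3 at 1.60, glutamine synthetase, Glul, at 1.60, Tef at 1.36, Ccdc141 at 1.32 and the GTPase Gem at 1.75, and on the other side Wnt7a at −1.82, Acoxl at −2.88 and the gastrokine Gkn2 at −2.04. No gene rose, and 1417 genes had an unadjusted p under 0.05. DESeq2 called 193 genes, limma voom called 1, limma trend called 0, and edgeR called 426 with no filter on low counts, 1 with the ribosomal RNA share as a term, 5 with libraries thinned to equal protein-coding counts, and 0 with RLE or upper-quartile factors, a mean count of at least 50, a sex term, a 2-group or additive fit, protein-coding genes only, libraries thinned to equal totals, or GC and length trends removed. Moxd1 had 0 and 2 counts in combination replicates 1 and 2, so its size without combination replicate 2 is not finite. The count was 43 without combination replicate 1, 24 without JQ1 replicate 1 and 0 without any of the other 6 libraries, left out singly.

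Clock genes led the lists for the antibody averaged over both backgrounds, and most lists had the larger median in the combination against JQ1. Their median was 0.95 with 15 of 17 positive, none past the test over all genes and 8 risen adjusted over the list alone (camera adjusted p = 1.07e-13; adjusted p = 0.39 with an estimated correlation). DNA replication (median −0.70, Mcm2 at −1.61), ribosome biogenesis (−0.45, Nop56 at −1.15) and MAPK output (−0.56, Etv4 at −1.12) were lower with 26 of 27, 25 of 26 and 17 of 17 negative, and 1, 5 and 0 fell adjusted over the list alone (9.91e-08, 1.27e-07 and 2.01e-07; the lowest adjusted p = 0.39 with an estimated correlation). Gut-like differentiation (−0.74, Vil1 at −1.27), histone (−0.34), mitosis (−0.46) and BET-repressed genes (−0.46) were lower, and endothelium (0.30), p53 targets (0.22, Sesn1 at 1.5), NRF2 targets (0.33), interferon gamma (0.66) and airway genes (0.49) higher, at a camera adjusted p of 0.000416 to 0.0305, with the lowest adjusted p = 0.39 with an estimated correlation. None of their members passed over all genes, and adjusted over the list alone 2, 2, 0 and 1 fell in the lower lists and 0, 3, 2, 0 and 1 rose in the higher ones, in the order given. The medians for the antibody without JQ1 and with it were −0.18 and 0.98 for NRF2 targets, 0.038 and −0.84 for mitosis, 0.025 and −1.16 for gut-like differentiation and 1.02 and −0.28 for airway genes, which have opposite signs. They were −0.080 and −1.43 for DNA replication, −0.175 and −0.71 for ribosome biogenesis, −0.21 and −0.95 for MAPK output, −0.035 and −0.55 for histones, −0.047 and −0.52 for BET-repressed genes, 0.42 and 1.49 for the clock, 0.20 and 0.82 for interferon gamma, 0.20 and 0.32 for p53 targets and 0.49 and 0.36 for endothelium. Calls ended for BET-repressed genes without vehicle replicate 2, JQ1 replicate 1, anti-PD-1 replicate 2 or combination replicate 2, for mitosis without JQ1 replicate 1, anti-PD-1 replicate 2 or combination replicate 1 or with a sex term, and for airway without JQ1 replicate 2, anti-PD-1 replicate 1 or combination replicate 1, with limma voom or with a sex term. They also ended without JQ1 replicate 1 for gut-like differentiation, without anti-PD-1 replicate 2 for NRF2 targets, without combination replicate 1 for histones, without combination replicate 2 for p53 targets, and for interferon gamma without JQ1 replicate 2 or combination replicate 2. The airway test turned direction without combination replicate 1. Ribosomal RNA was 24.4% ± 0.506 and 49.9% ± 4.67 in the groups with the antibody and 23.4% ± 1.38 and 32.1% ± 5.13 in those without.

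The interaction asks whether JQ1 acted differently with and without the antibody. Prdx6 stood at 2.38 (SE 0.42), Per3 at 2.35 (SE 0.45), Pgd, of the pentose phosphate pathway, at 1.66, Trim6 at 2.91 and Ttc38 at 2.53, and on the other side Mhrt at −4.30 (0 and 2 counts in combination replicates 1 and 2), Thbs3 at −2.73, Antxr1 at −2.46 and Tuba1a at −1.98. None passed: edgeR's quasi-likelihood test with Benjamini-Hochberg called 0 genes, the smallest adjusted p was 0.745, and 881 genes had an unadjusted p under 0.05 where chance gives 704. DESeq2 called 18 genes, limma voom called 0, limma trend called 0 and edgeR with no filter on low counts called 138. Without JQ1 replicate 1 the count was 1.

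Log2 fold changes of JQ1 without the antibody and with it, 2 contrasts that share no library, correlated across the 14085 genes with a Pearson r of 0.424 and a Spearman rho of 0.528. Of the 596 genes called for JQ1 in the presence of the antibody, 558 (93.6%) had the same sign without it, where all genes had the same sign in 73.1%. With no filter on low counts the r was 0.127, and without 1 library 0.192 to 0.377. Both contrasts set higher ribosomal RNA shares against lower ones, so JQ1 cannot be told apart from the share here. For the antibody without and with JQ1 the Pearson r was 0.114 and the Spearman rho 0.139, with 55.0% of all genes of the same sign. It was 0.0178 with no filter on low counts, 0.21 at a mean count of at least 50 and −0.0154 to 0.154 without 1 library. These are correlations across genes, which are not independent replicates, so no p is given. Across all 6 contrasts with list tests, 0 of the 81 list calls had a median that turned sign with RLE or upper-quartile factors.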

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

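Chosen only after the results were seen were the S phase, time-of-day and glucocorticoid tests, the list tests of the interaction, and the counts with libraries thinned, protein-coding genes only, GC and length trends removed and the ribosomal RNA share as a term.

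A test of the difference itself set 15 gene lists apart between the JQ1 effect without the antibody and with it, by camera at the preset correlation on the interaction. The ribosomal RNA share differed in the same way, from 23.4% to 32.1% with JQ1 alone and from 24.4% to 49.9% with JQ1 on the antibody. NRF2 targets had an interaction median of 1.16 (n = 14 genes; camera adjusted p = 9.46e-09), from −0.088 with JQ1 alone to 1.66 with JQ1 on the antibody. Cholesterol synthesis genes were at 0.86 (6.59e-05; 0.22 and 1.39), clock genes at 1.08 (0.000142; −0.11 and 0.76) and alveolar type 2 markers at 0.40 (0.0122; −0.59 and 0.52). Lower with JQ1 on the antibody were DNA replication genes, at −1.36 (1.02e-07; 0.056 and −1.24), ribosome biogenesis, at −0.62 (0.000236; 0.15 and −0.46), gut-like differentiation, at −1.24 (0.00321; 0.61 and −0.76), and striated muscle, at −1.85 (0.00321; −0.63 and −2.46). The T cell list was at −1.58 (0.00713; 0.15 and −1.44), with 5 of its 22 members tested. Zap70 had 0 counts in vehicle, and Bcl11b and Tcf7 made up most CPM there. Fibroblast and matrix genes were at −0.50 (0.00991; −0.17 and −0.62), mesenchymal transition at −0.63 (0.0122; 0.19 and −0.84) and macrophage markers at −0.73 (0.0161; 0.64 and −0.19). MAPK output was at −0.80 (0.0161; −0.14 and −0.74), mitosis at −1.02 (0.0161; −0.48 and −1.34) and the histone list at −0.44 (0.0174; −0.83 and −1.40). None holds: the lowest adjusted p = 0.518 with an estimated correlation. No single gene passed the interaction in edgeR's quasi-likelihood test, and DESeq2 called 18. Groups of 2 libraries are too small to test whether a single library stands apart. Striated muscle was at 1.7 and −0.54 against the vehicle mean in anti-PD-1 replicates 1 and 2, so −2.46 rests mostly on replicate 1.

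The 676 genes called in the combination against vehicle came with a ribosomal RNA share of 49.9% against 23.4%. Lower depth and GC or length bias are each argued against as the whole cause, since 531 genes were called with libraries thinned to equal totals, 522 thinned to equal protein-coding counts and 782 with GC and length trends removed. The 595 genes called among protein-coding genes alone decide nothing on a uniform dilution by ribosomal reads, which is 1 factor per library and is already removed by the TMM factors. A gene-specific response to what raised the ribosomal RNA share cannot be told apart from treatment, since both groups with JQ1 have the higher shares. With the share as a term 0 genes were called. The slope of that term came only from differences within pairs of libraries, so this count decides nothing. Differences within pairs that went with a higher share correlated with the JQ1 effect in other libraries at 0.014 and −0.0185, which decides nothing. A response of the tumours to treatment stays open as a hypothesis.

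Clock genes were higher in the combination against vehicle, with Per3, Tef, Ciart and Per2 called. A different time of day at sampling could raise them, and would be expected to lower the Arntl arm (Arntl, Clock, Npas2, Cry1, Nfil3), which had a median of 0.20 (SE 0.67, n = 5 genes) beside 1.49 (SE 0.35, n = 12 genes) in the other clock genes. Time of day cannot be told apart from treatment for these genes, as the labels give no sampling time and the spread of the arm is wide. For glucocorticoid exposure, a list of receptor targets outside the clock, made before their values were seen, had a median of 1.56 (SE over genes 0.33, n = 12 genes; camera adjusted p = 0.000249; adjusted p = 0.578 with an estimated correlation), which goes with such exposure, and Fkbp5, named here after its values were seen, was its only called member, at 2.11 (SE 0.41; adjusted p = 0.0303 by edgeR's quasi-likelihood test). Combination replicate 2 carried most of it: against the vehicle mean the list median was 2.12 in that library and 0.75 in combination replicate 1, and whether exposure came from handling, illness or treatment was not tested.

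Histone genes were lower with JQ1 alone, by a median of −0.83 in the list and −1.06 in the cluster family. Fewer cells in S phase cannot be told apart from other explanations here, since the median of the DNA replication genes was 0.056 with a spread of 0.56 (SD) between the JQ1 libraries. Against the vehicle mean, JQ1 replicate 1 had list medians of −0.67 for histones, 0.48 for DNA replication and −0.175 for mitosis, and JQ1 replicate 2 had −1.03, −0.32 and −0.57. Reads shared between near-identical histone genes also stay open, as how they were counted is not given in the sources used here. A direct effect of JQ1 on histone transcription may be involved and was not tested.

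For JQ1 over both backgrounds, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes in a 2-group fit. It called 572 genes and the highest other split called 2, which argues against a random split as the source. For anti-PD-1 over both backgrounds the real split called 0 genes in that fit, so all 35 splits gave as many by construction and the count of splits says nothing about chance. The highest other there was 572, in the split by JQ1, which points to JQ1, or to what goes with it in these libraries, as a structure of the samples.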

How the results depend on the processing

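Chosen only after seeing the data were the alternatives without ribosomal RNA genes, with protein-coding genes only, libraries thinned to equal totals or equal protein-coding counts, GC and length trends removed, recovered reads and the ribosomal RNA share as a term, and for lists the sex term. Where no cause is given below, the cause was not tested. No paired analysis was possible because the labels give no replicate numbers that link libraries across groups. Where a library was left out, the lone library of its group is assumed to vary like the other groups. The smallest library, with 2719816 counts, limits what can be tested in the combination, and simulated 2-fold changes there were recovered in 1.49%.

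Counts of called genes, given in the order JQ1, anti-PD-1, combination against vehicle, combination against JQ1, combination against anti-PD-1, JQ1 over both backgrounds, anti-PD-1 over both backgrounds and interaction, were 0, 0, 676, 3, 596, 1166, 2 and 0. With no filter on low counts they were 250, 55, 1992, 672, 1920, 2527, 426 and 138, and with DESeq2 86, 11, 1665, 417, 1594, 2158, 193 and 18. limma voom called 1 for JQ1, 5 for the combination against JQ1 and 1 for anti-PD-1 over both backgrounds, and limma trend 8 and 0 for the latter 2. With only the libraries compared, which leaves fewer samples, the count was 1 for JQ1, 245 for the combination against vehicle, 0 against JQ1 and 57 against anti-PD-1. With a sex term it was 339, 0 and 212 for the combination against vehicle, JQ1 and anti-PD-1, and 0 for anti-PD-1 over both backgrounds. With the ribosomal RNA share as a term it was 0, 1 and 0 for the combination in that order, 0 for JQ1 over both backgrounds and 1 for anti-PD-1 over both backgrounds. The combination against JQ1 gave 5 with libraries thinned to equal totals and 6 with GC and length trends removed. JQ1 over both backgrounds gave 572 in a 2-group fit. Thinned to equal protein-coding counts, the combination against JQ1 gave 26, JQ1 over both backgrounds 700 and anti-PD-1 over both backgrounds 5. Anti-PD-1 over both backgrounds gave 0 with RLE, upper-quartile factors, a mean count of at least 50, a 2-group fit, an additive fit, protein-coding genes only, libraries thinned to equal totals, and GC and length trends removed. Leaving out 1 library gave 0 to 17, 0 to 1, 7 to 1115, 0 to 114, 3 to 967, 17 to 1716, 0 to 43 and 0 to 1.

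Lists past the test were 11 for JQ1, 10 for anti-PD-1, 17 for the combination, 15 for JQ1 over both backgrounds and 13 for anti-PD-1 over both backgrounds, and 0 in each of the 5 with an estimated correlation. The sex term gave 6 for JQ1 and 16 for anti-PD-1, and no filter on low counts 18 for anti-PD-1. Leaving out 1 library gave 9 to 14, 9 to 15, 14 to 18, 13 to 18 and 11 to 16. The correlation of the JQ1 effects was 0.127 with no filter on low counts, 0.564 at a mean count of at least 50 and 0.192 to 0.377 without 1 library, and that of the antibody effects, 0.114, was 0.0178 and 0.21 at those settings and −0.0154 to 0.154 without 1 library, turning negative without combination replicate 2 (−0.0154) and JQ1 replicate 2 (−0.0102).

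Of 894 results of named genes 162 were called. There were 27 alternatives, each of which covered 79 to 162 of these calls, and with the ribosomal RNA share as a term 31 turned direction, while under the other alternatives none of the calls covered did. In the combination against vehicle these were Arl4d at −1.75, Dcn −0.45, Epha4 0.79, Gbp2 −2.49, Gfra1 −0.41, Iigp1 −2.29, Klf15 −1.11, Mycn 0.50, Napsa −0.86 and Sqle −0.84. Against anti-PD-1 they were Adam28 at −2.11, Gfra1 −1.98, Iigp1 −2.16, Mycn 0.12 and Orm1 −0.10. For JQ1 over both backgrounds they were Bcas1 at −2.54, Dpcr1 −1.10, Epha4 0.54, Gbp2 −1.91, Iigp1 −1.49, Kcnip4 4.75, Krt20 −3.01, Muc3 −0.29, Mycn 0.65, Myh6 0.061, Napsa −0.45, Per3 −0.48, Sptssb −3.56, Sqle −0.37, Sult1d1 −7.08 and Tkt −0.31. The share was higher in both groups with JQ1, so what the term removes cannot be told apart from treatment.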

Other observations

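Genes of the unfolded protein response went both ways in the combination against vehicle: Ppp1r15a, which reverses the stress block on translation, rose by 2.15 (1.02 without combination replicate 2), while the secreted factor Manf and the chaperone Hyou1 fell by 1.70 and 1.18. Among 17 such genes 14 did not pass, adjusted over the list alone 3 rose and 3 fell, and the median was −0.07 (camera adjusted p = 0.723), with the signs of the median, mean and test not all the same. The immediate early genes Cyr61 and Egr1 fell by 2.34 (3.08 without combination replicate 2) and 1.61, with 21 of 23 not passing, 1 risen and 2 fallen adjusted over the list alone, and a median of −0.08 (0.723). The brush border gene Vil1 fell by 1.63, with a list median of −0.76 (0.0951). The angiogenic factor Vegfa fell by 1.36. MHC class I genes had a median of 0.44 (0.747) and none passed. Their medians against the vehicle mean were −0.55 and 0.53 in combination replicates 1 and 2, and their summed CPM was 2710.6 ± 395.6 against 4566.8 ± 1153.8 in vehicle (n = 2 each).

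Several cell types had too few tested genes for a list test, and their summed CPM rest on single genes or libraries, so genes are given instead, in the order vehicle, JQ1, anti-PD-1 and combination (n = 2 each). Mesothelin, Msln, a gene of mesothelium also expressed by some carcinomas, was at 12.6 ± 5.76, 32.9 ± 10.6, 5.43 ± 6.79 and 65.2 ± 21.3 CPM. Other mesothelial markers had few counts. Upk3b was at 0.115, 0, 0.235 and 1.17 CPM, Muc16 at 0.0764, 0.131, 0.645 and 1.17 CPM, and Upk1b at 0.774, 1.66, 2.4 and 1.47 CPM. Combination replicate 1 held 4, 4 and 7 counts of Upk3b, Muc16 and Upk1b, and combination replicate 2 held 4, 4 and 0. Wt1 was at 0.162 and 0.0824 CPM in these groups. Fabp4, of adipocytes, endothelium and macrophages, was at 1.81 ± 0.0383, 6.33 ± 3.62, 2.09 ± 0.302 and 9.16 ± 5.5 CPM. Cidec was at 0.335, 0.908, 0.117 and 0.952 CPM on 42 counts in all, and Adipoq, Lep, Retn, Cfd and Ucp1 had 0 counts in every library. With probe capture, 0 counts need not mean absence.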
